A study of Eucalyptus tereticornis with 4 samples.

How the data were processed

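Total RNA of developing xylem from 4 provenances of Eucalyptus tereticornis was labelled with Cy3 through oligo-dT primed cDNA and in vitro transcription and hybridised to a custom one-colour Agilent Eucalyptus array, per the labels' protocols. The 4 arrays lay on 1 slide and were scanned together, so slide and scan could not be tested as batches. The array position followed the groups. Each scanner file holds intensity values per spot, which were made with Agilent Feature Extraction 11.5.1.1, per the file headers. Per the file headers, the processed intensity is background-subtracted and detrended within the array, spots not above background get surrogate values, and nothing is normalized between arrays. The deposited value table of the series holds log2 values. Set against the scanner intensities, each of its columns equals log2 of the processed intensity minus the array's 75th percentile, within 0.000587, with column medians between -3.83 and -3.43. Its scale, centring and direction are therefore known, though the step is not given in the sources used here. It was used as an alternative. The files also hold flags per spot, as 0 or 1, which per the file headers mark other properties such as outliers and signals well above background.

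Here, control spots and the 12 spot values flagged as outliers were left out, and log2 of the processed intensity was centred on each array's 75th percentile. Each probe was spotted once. A probe was tested where it was well above background on both arrays of at least 1 group, which kept 38164 of 61657 probes. The groups were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all probes tested and a threshold of 0.05. Where a probe was not well above background on any array of a group, the fold is a bound. It sets the bright group's mean against the mean, over the dim group's arrays, of the higher of the probe's own value and the lowest value of any probe well above background on that array, and is written as at least N-fold. It is given only for a gene of which no other probe was well above background in the dim group. No fold is given in the other cases in which a group had a dim array. Gene names are those of the array files, which are those of the array's design. Of all probes 7914 have a gene description and an Arabidopsis locus, among them 2623 tested probes of 1542 gene models. The other 30214 contig probes, 4994 EST probes and further tested probes without a description were counted but not named. Of the tested probes 7282 are named as cross-hybridizing by the array's design. Among the genes named below, these are the probes of Eucgr.B01448, RD29B, AtGolS2 (Eucgr.L00245), SKOR, Eucgr.B02886, CESA3 (Eucgr.G03380), ATCAD1, CCOAMT, AtMYB103 and ATMYBR1. Further ones are those of RD26, PG2, GATL3, ATEXLB1, ATEXPA13, Eucgr.C02646, Eucgr.E03810, SR33 and Eucgr.L02712. No other probe of these genes was tested. Genome positions are not reported, since no genome was used here.

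The 33 gene lists, the alternatives other than those named as added, the tests and the rule for named genes were fixed before the data were examined. Fits of these tests were run in an exploratory way before the final ones. Lists were matched on the text of the gene descriptions and on Arabidopsis loci. They were tested with camera of limma against the other described genes at a preset correlation of 0.01, two-sided, with the brightest probe per gene, where at least 5 genes were tested, with adjustment over the 18 such lists. A gene was read as a gene model identifier, since several models share one Arabidopsis symbol, a reading settled after the data were seen, and symbols were tried as an alternative. The median difference of a list was also placed among 10000 random lists of the same size matched on mean expression in 10 classes. Over all tested described genes the median difference was 0.14. Lists with fewer tested genes are given here as medians: class III peroxidases with 2 genes at 1.57, cellulose accessory genes with 3 at -0.14, fasciclin-like arabinogalactan proteins with 4 at -0.09, WRKY genes with 4 at 0.05, the methionine cycle with 1 at -0.47, xylem cell death with 2 at 0.97, gibberellin with 3 at 0.14, cytokinin and brassinosteroid with 2 at -0.27, aquaporins with 1 at 0.001, terpene synthases with 1 at 0.40, ribosomal proteins with 2 at 1.12 and phloem markers with 3 at 0.41. The xylan and mannan list, the cork and suberin list and the list of fungal and bacterial genes had 0 tested genes.

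Named genes are described genes, one probe per gene, taken by rule. As no probe passed the threshold, the 10 with the widest gap between the groups are given in each direction, a gap being the lowest value of the higher group minus the highest of the lower group. Added to them are the 3 members with the lowest p of each tested list, the brightest member of each monolignol enzyme and cellulose synthase subunit, and, for each provenance, the 3 probes farthest above and the 3 farthest below all other arrays. A probe stood apart on an array if its value was at least 1 log2 unit above or below each other array and the brighter side was well above background, which was read as all 3 brighter arrays for a probe below. This reading was settled after the numbers with at least 1 bright array had been seen, 2933 in place of 2653 for SW Mt. Garnet, and the looser one was kept as an alternative. The groupings were compared by the number of probes whose 2 pairs of arrays did not overlap, with a gap of at least 1.

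The alternatives were quantile normalization, median centring, normexp background correction with offset 50 on the mean and local background intensities, no filter on dim probes, a filter on all 4 arrays, eBayes with an intensity trend and robust settings, the mean over a gene's probes, the value table, each array left out in turn, a threshold of 0.10, a rule of groups without overlap, an estimated correlation, all probes of a list, a gap of 0.5 and a difference of 2. Alternatives added after seeing the data were lists and counts without cross-hybridizing probes, all tested genes as background, genes joined by symbol, at least 1 bright array for a probe below, an estimated correlation in each setting under which a list passed, and the groupings on probes well above background on all 4 arrays. An uncalled value that changed sign under an alternative was counted as a sign change and not as a reversed call. With an array left out or another filter, the tested genes of a list were chosen anew, so their number could change. The test was checked on simulated data with the means and the spread of these 38164 probes and 50 changed probes of each size in 20 simulations. It recovered 0% of changes of 1 and of 2 log2 units, 0.1% of changes of 4 and 47.3% of changes of 8, with 1.35 false calls per simulation on average. Of simulated lists of 8 genes shifted by 1 log2 unit, 95.5% had a camera p under 0.05, and of unshifted lists 4.5%. These simulated genes varied independently of each other.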

Results

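Gene expression was measured in developing xylem, the layer of differentiating wood beneath the cambium, of Eucalyptus tereticornis, a forest red gum grown for pulp and timber. The trees were 19 years old. The labels name 4 provenances, that is, seed origins, and 1 sample was hybridised from each. SW Mt. Garnet and Cardwell were labelled as high in holocellulose, the polysaccharide fraction of wood, and Kupiano and N Kennedy River as high in lignin, its phenolic polymer, so each group held 2 arrays. Each array was a one-colour oligonucleotide array of 61657 Eucalyptus probes besides its controls. The share of probes well above background was 67.8% on the SW Mt. Garnet array, 61.1% on the Cardwell array, 60.9% on the Kupiano array and 69.7% on the N Kennedy River array, and no spot was saturated. Median signals lay between 64.6 and 83.3 intensity units. The number of arrays limits the precision of every comparison, and because each array of a group came from another provenance, a group's SD is the spread between 2 provenances. The labels do not state how many trees stood behind a sample. All values are log2 signals relative to the 75th percentile of their array, and differences are high lignin minus high holocellulose, given with the standard error of the limma fit for the probe a gene is named by.

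The first comparison asked which transcripts separated the high lignin from the high holocellulose samples. Among the described genes, the widest gap in favour of high lignin was at an HXXXD-type acyltransferase, Eucgr.B01448, a member of a family that transfers acyl groups from coenzyme A. It stood at -0.18 ± 0.58 (SD, n = 2) in high lignin and at -7.13 ± 0.95 (SD, n = 2) in high holocellulose, where 1 of 2 arrays measured it well above background (adjusted p = 0.362, limma). RD29B (Eucgr.A02790), a gene known for its response to dehydration and abscisic acid, stood at 0.99 ± 0.12 against -4.53 ± 1.80, also with 1 of 2 high holocellulose arrays well above background (adjusted p = 0.593, limma), and galactinol synthase AtGolS2 (Eucgr.L00245), an enzyme of raffinose sugar synthesis, was at least 5.96-fold brighter in high lignin (adjusted p = 0.414, limma). In the other direction the widest gap was at a small heat shock protein gene, HSP18.2 (Eucgr.J01972), at 0.02 ± 0.41 in high holocellulose and not well above background in high lignin (adjusted p = 0.316, limma). Other probes of this gene were well above background on all 4 arrays and differed by -2.81 and -1.68. The acyl-activating enzyme AAE7 (Eucgr.A00203) stood at -0.92 ± 2.67 in high holocellulose and was not well above background in high lignin (adjusted p = 0.642, limma), while another probe of it, well above background on 1 of 2 high lignin arrays, differed by -5.41. None of these genes passed the test. The probes of Eucgr.B01448, RD29B and AtGolS2 are named as cross-hybridizing by the array's design, and no other probe of these genes was tested. Genome positions are not reported, since no genome was used.

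**Figure D1:**
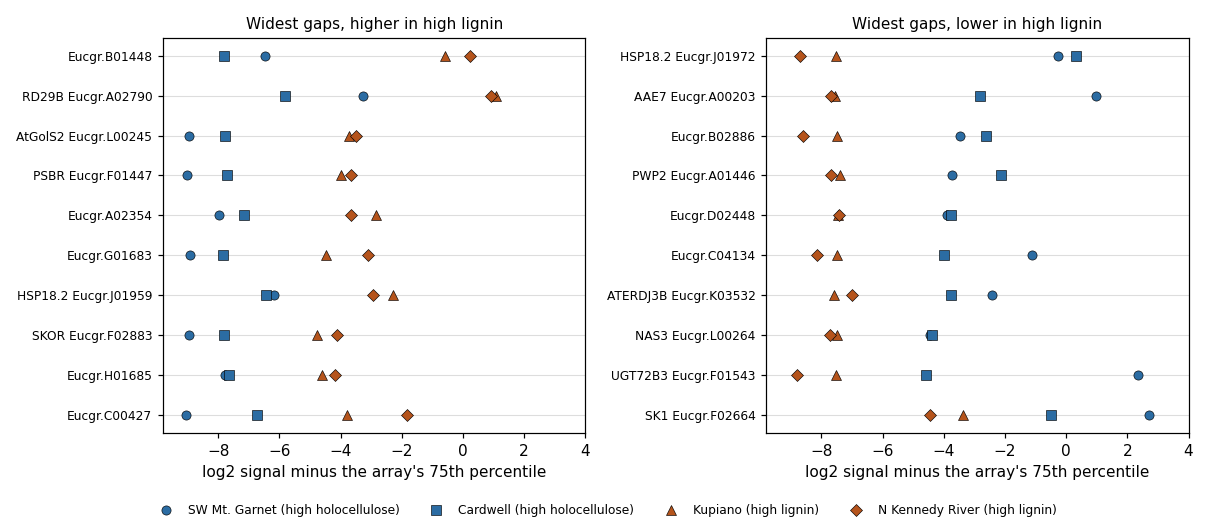
Log2 signal minus the array's 75th percentile (horizontal axis) for the 10 described genes with the widest gap between the groups in each direction, one probe per gene; each point is 1 array, shaped by provenance and coloured by group. The points of the 2 groups do not overlap in any row. In 16 of the 20 rows the lower group was not well above background on either array, so its points are values given by the scanner software to such spots. SK1 Eucgr.F02664, well above background on all 4 arrays, has a gap of 2.88 log2 units.

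The remaining genes with wide gaps came from several functions. An insulinase-type peptidase (Eucgr.A02354) was at least 7.65-fold brighter in high lignin, and the outward-rectifying potassium channel SKOR (Eucgr.F02883), known for loading potassium into the xylem, at least 3.37-fold. For 9 of the 20 genes the probe with the widest gap was not well above background in the lower group but another probe of the gene was on at least 1 array, so no bound is given for these genes. Among them, the photosystem II subunit PSBR (Eucgr.F01447) differed by 2.09 with another probe, well above background on 1 of 2 high holocellulose arrays. A further PSBR probe, too dim to be tested, differed by 0.26. It was well above background on 1 high holocellulose array and on no high lignin array. With another probe well above background on all 4 arrays, a basic helix-loop-helix protein (Eucgr.G01683) differed by 1.76 and a TIR-NBS-LRR resistance protein (Eucgr.C00427) by 2.68 (6.39-fold). A further Eucgr.C00427 probe, too dim to be tested, differed by 0.86 and was well above background on 1 array of each group. A protein kinase (Eucgr.H01685) differed by 0.95 with another probe, too dim to be tested and well above background on 1 array of each group. A second HSP18.2 model (Eucgr.J01959) went the opposite way from the first, with -2.62 ± 0.47 in high lignin and -6.29 ± 0.18 in high holocellulose, where 1 of 2 arrays was well above background. Brighter in high holocellulose were a methyltransferase (Eucgr.B02886) at least 7.38-fold, an EF-hand calcium-binding protein (Eucgr.D02448) at least 4.30-fold, the chaperone ATERDJ3B (Eucgr.K03532) at least 7.14-fold and nicotianamine synthase NAS3 (Eucgr.L00264) at least 2.85-fold. The ribosome assembly factor PWP2 (Eucgr.A01446) differed by -4.08 with another probe, well above background on all 4 arrays. For a Clp protease/crotonase family protein (Eucgr.C04134), another probe, too dim to be tested and well above background on 1 array of each group, differed by -0.50, and a further one was well above background on no array. The glucosyltransferase UGT72B3 (Eucgr.F01543) stood at 2.35 on the SW Mt. Garnet array and at -4.60 on the Cardwell array, and differed by -4.63 with another probe, well above background on 1 of 2 high lignin arrays. Shikimate kinase SK1 (Eucgr.F02664), on the route to phenylalanine, stood at 2.69 and -0.49 on the high holocellulose arrays and at -3.37 and -4.45 on the high lignin arrays. For these 15 genes the adjusted p of the limma fit ran from 0.405 to 0.783. Other tested probes of the same gene pointed the same way wherever there were any, though not always as far. SKOR and Eucgr.B02886, read by probes named as cross-hybridizing, had no other tested probe. After normexp background correction the median ratio of the named probes' differences to those given here was 0.48.

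Over all 38164 probes tested, limma with Benjamini-Hochberg adjustment put 0 probes higher and 0 lower in high lignin, and the smallest adjusted p was 0.308. At an unadjusted p under 0.05 there were 2336 probes, 1420 higher and 916 lower, where 1908 were expected by chance. The filter, set by the labelled groups, favoured such probes. SW Mt. Garnet with Kupiano against the other 2 arrays gave 1633, and SW Mt. Garnet with N Kennedy River 1032. The intensity-trended, robust version of the test also gave 0 in both directions, with 2251 probes at an unadjusted p under 0.05. A permutation of 2 arrays against 2 cannot give a p below 0.333, and on simulated arrays of the same spread the test recovered 0.1% of probes changed by 4 log2 units and 47.3% of those changed by 8, so smaller differences were not detectable with these arrays.

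Differences of genes matched to the lignin pathway had both signs. The 2 that separated the groups, PAL2 and 4CL3, were lower in high lignin, though neither passed the test. The array's descriptions do not tell whether they serve lignin or flavonoids. Of 8 tested members of monolignol biosynthesis, 0 passed the test, over all probes or adjusted over the list alone. The median difference was -0.71, at percentile 1.1 of the random lists matched on mean expression. Of the 8, 0 stood higher and 2 lower on both high lignin arrays, where 24.1% and 16.4% of all described genes did. PAL2 (Eucgr.J00907), phenylalanine ammonia-lyase at the entry of the pathway, stood at 2.84 ± 1.03 (SD, n = 2) in high holocellulose and 0.50 ± 0.96 in high lignin, a difference of -2.34 ± 0.76 (SE). The coenzyme A ligase 4CL3 (Eucgr.K00087) differed by -2.49 ± 0.76, with -0.97 ± 1.25 in high holocellulose and -3.46 ± 0.66 in high lignin. Further along the pathway, the brightest ferulate hydroxylase (FAH1, Eucgr.I00335) differed by -1.06 ± 1.02, the brightest O-methyltransferase (ATOMT1, Eucgr.F02623) by 1.22 ± 1.20, the alcohol dehydrogenase ATCAD1 (Eucgr.L01277) by 0.42 ± 0.56 and CCOAMT (Eucgr.H04648) by -0.53 ± 2.37. A second O-methyltransferase model (Eucgr.A01395) differed by 2.47 ± 1.67. CCOAMT and this model were well above background on 1 of 2 high holocellulose arrays. By camera, which sets a list against the other described genes, the list had an adjusted p of 0.839 and 0.873 with an estimated correlation. Its median was 0.59 without Kupiano, -0.15 without Cardwell, -0.43 without SW Mt. Garnet, -0.27 with normexp, -0.40 with the mean over the probes of a gene and 0.38 without the filter on dim probes.

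Among 5 tested laccases, the oxidases that join monolignols in the wall, 0 passed over all probes and 1 passed adjusted over the list alone. This was LAC14 (Eucgr.F04158), at -3.67 ± 0.37 in high lignin and -5.67 ± 0.22 in high holocellulose, where 1 of 2 arrays was well above background. A LAC17 model (Eucgr.F04159) lay the other way, at -3.22 ± 0.78 and -1.35 ± 0.19, and a further LAC17 model (Eucgr.A01282) differed by 0.40 ± 0.66. The list's median of -0.35 had a camera adjusted p of 0.839 and was 0.19 without SW Mt. Garnet, -0.89 without Cardwell, -0.04 without Kupiano and 0.46 without N Kennedy River. It was 0.25 without the filter on dim probes, 0.03 with the mean over the probes of a gene, -0.02 with normexp, -0.60 with median centring and -0.56 with quantile normalization. The 5 cellulose synthase genes had a median difference of 0.34, at percentile 53.1 of the random lists, and 0 passed. This median was -0.0006 without SW Mt. Garnet, 0.68 without Cardwell, 0.04 without Kupiano and 0.85 without N Kennedy River, 0.04 with quantile normalization and 0.10 with median centring. CESA3 (Eucgr.G03380) differed by 0.65 ± 0.38, a second CESA3 model (Eucgr.J01278) by 0.34 ± 0.67 and CESA1 (Eucgr.C02801) by 0.45 ± 1.45. IRX3 (Eucgr.H00189), a subunit known from the secondary wall, differed by -0.30 ± 1.89 and by 0.54 after normexp background correction. It stood at -2.95 on the Kupiano array and at -8.24, not well above background, on the N Kennedy River array. The camera adjusted p was 0.839. The 2 tested class III peroxidases had a median of 1.57 (1.27 with a gene not well above background in 1 group at its bound). The 3 cellulose accessory genes had a median of -0.14 and the 4 fasciclin-like arabinogalactan proteins one of -0.09. These were too few for a list test. No xylan or mannan gene with a description was tested, and probes without a description could not be matched to any list.

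**Figure D2:**
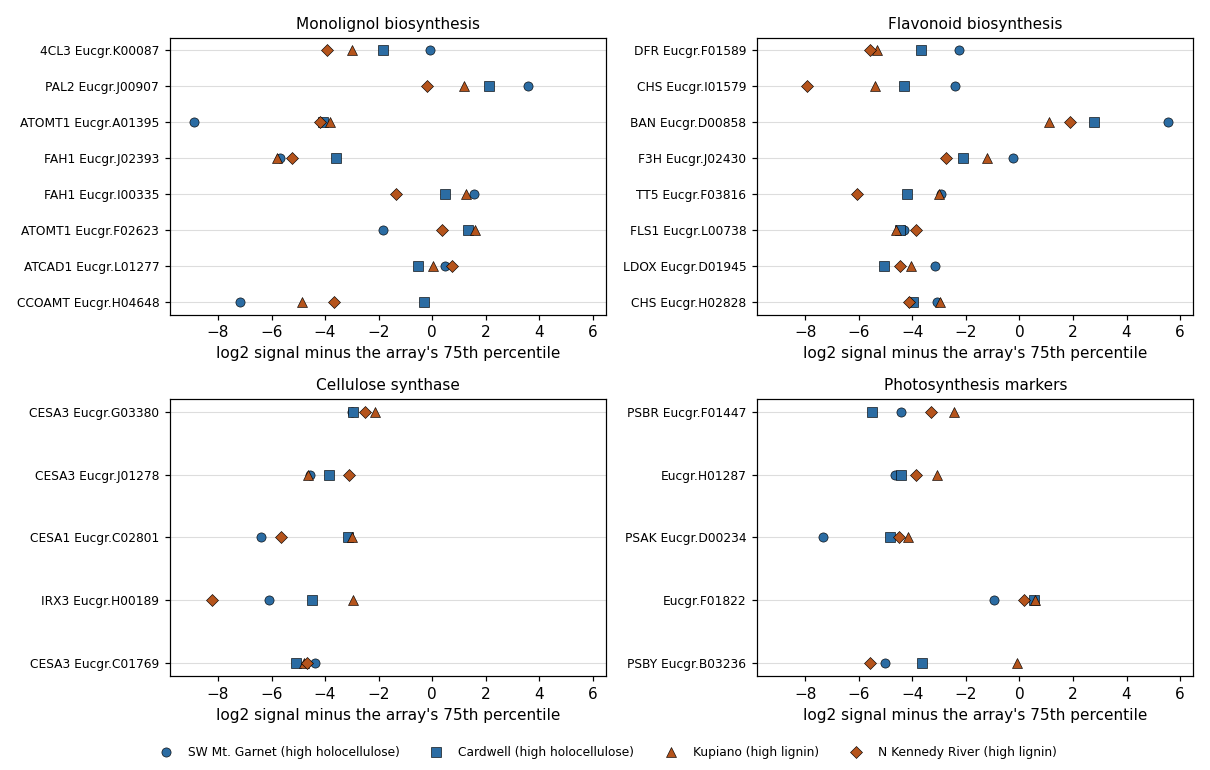
Log2 signal minus the array's 75th percentile (horizontal axis) for the tested members of 4 gene lists, the brightest probe per gene, ordered by p; each point is 1 array, shaped by provenance and coloured by group. PAL2, 4CL3, DFR and BAN lie lower on both high lignin arrays, while the cellulose synthase genes overlap except CESA3 Eucgr.G03380, with a gap of 0.44.

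The branch to flavonoids had a negative median difference. Of its 8 tested genes 0 passed the test over all probes or adjusted over the list alone. The median difference was -0.88, at percentile 0.51 of 10000 random lists matched on mean expression, and the camera adjusted p was 0.115, or 0.873 with an estimated correlation. Dihydroflavonol reductase DFR (Eucgr.F01589) differed by -2.50 ± 0.60, with 1 of 2 high lignin arrays well above background, but by -0.46 with another probe, well above background on all 4 arrays. A chalcone synthase (CHS, Eucgr.I01579) was at least 5.96-fold brighter in high holocellulose (adjusted p = 0.783, limma), and the anthocyanidin reductase BAN (Eucgr.D00858) differed by -2.66 ± 1.04. The list's median depended on single arrays. It was -0.09 without SW Mt. Garnet and -0.14 without N Kennedy River, with camera adjusted p of 0.879 and 0.691, and -1.66 without Cardwell, with a camera adjusted p of 0.0119, or 0.976 with an estimated correlation. With the mean over the probes of a gene it was -1.05, with a camera adjusted p of 0.0382, or 0.913 with an estimated correlation. It was -0.49 with normexp, -0.46 with the filter on all 4 arrays and -0.25 without the filter on dim probes. The 5 shikimate and phenylalanine genes had a median of 0.14 and a mean of -0.74, with a camera adjusted p of 0.839. The median was -0.14 with quantile normalization, -0.11 with median centring and -0.44 without SW Mt. Garnet. It was -0.26 over 8 genes without Cardwell, 0.51 over 7 without Kupiano and -0.09 over 6 without N Kennedy River. Apart from SK1, EMB3004 (Eucgr.H04428) differed by -0.90 ± 0.47 and the arogenate dehydratase ADT1 (Eucgr.E04043) by 0.82 ± 0.44.

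Photosynthesis genes, fixed as markers of green tissue, had a median difference of 1.51 over 5 tested genes, at percentile 99.4 of the random lists, and 0 passed the test. The camera adjusted p was 0.254, and 0.873 with an estimated correlation. PSBR and PSAK passed the filter only through high lignin. The random lists were not matched on this, so the percentile cannot be read as support for a shift. The brightest PSBR probe stood at -2.88 ± 0.59 in high lignin and -4.97 ± 0.77 in high holocellulose. PSAK (Eucgr.D00234) differed by 1.75 ± 0.92. Both were well above background on 1 of 2 high holocellulose arrays. A PSBR probe too dim to be tested differed by 0.26. This dim probe was well above background on 1 high holocellulose array and on no high lignin array. A PsbP family gene (Eucgr.H01287) differed by 1.06 ± 0.45. By array, the mean of the 5 genes relative to the 4 arrays was 1.48 on Kupiano, -0.08 on N Kennedy River, -0.25 on Cardwell and -1.15 on SW Mt. Garnet. Without N Kennedy River, 10 genes could be tested and the median was 3.30. High lignin was then Kupiano alone, so the filter let in genes for being bright on that array. This median therefore cannot be read as support for a shift. The median was 0.51 over 7 genes without SW Mt. Garnet, 1.18 over 9 without Cardwell and 1.60 over 11 without Kupiano. With normexp it was 0.65, and without the filter on dim probes 1.06 over 23 genes. Of the 23 such genes on the array, 7 were well above background on no array. The 3 phloem markers stood at 0.38 on Kupiano, 0.02 on Cardwell, -0.09 on N Kennedy River and -0.30 on SW Mt. Garnet on the same scale, and the 8 cell division genes at 0.46 on Cardwell, 0.04 on N Kennedy River, -0.03 on Kupiano and -0.47 on SW Mt. Garnet. No cork or suberin marker with a description was tested.

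The 48 heat shock and chaperone genes had a median difference of 0.41, at percentile 99.5 of the random lists, but a camera adjusted p of 0.839. In this list 0 genes passed over all probes and 3 passed adjusted over the list alone, HSP18.2 Eucgr.J01959 at 2.95 ± 0.42, well above background on 1 of 2 high holocellulose arrays, HSP18.2 Eucgr.J01972 at -2.81 ± 0.45, and ATERDJ3B. The last was not well above background in high lignin, so its pass rests on values given by the scanner software, and only the bound of at least 7.14-fold holds. The median was -0.02 without SW Mt. Garnet, 0.65 without Cardwell and 0.16 with median centring. Of 15 defence proteins, 0 passed, and 6 stood higher on both high lignin arrays and 2 lower, where 24.1% and 16.4% of all described genes did. The median was 0.93, against 0.14 for all described genes. The CC-NBS-LRR gene Eucgr.H00722, well above background on 1 of 2 high holocellulose arrays, differed by 1.80 ± 0.38, the TIR-NBS-LRR gene Eucgr.C02646 by 2.69 ± 0.87 and Eucgr.E03125 by -1.43 ± 0.45. The list's median was -0.18 without SW Mt. Garnet, 0.17 without Cardwell and 0.50 with normexp. It was -0.15 without cross-hybridizing probes, -0.13 with all probes of the list, 0.23 without the filter on dim probes and 0.28 with the mean over the probes of a gene. Both lists had a camera adjusted p of 0.839.

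Regulators of the secondary wall went both ways. Of 5 tested NAC and MYB genes of this list 0 passed. MYB20 (Eucgr.F02864) differed by 1.68 ± 0.45, MYB83 (Eucgr.E01031), known as an activator of secondary wall synthesis, by 1.43 ± 0.83, and AtMYB103 (Eucgr.C02390) by -1.64 ± 0.55, around a median of 1.15, which was 0.35 without SW Mt. Garnet, 0.48 without N Kennedy River and 0.69 with normexp. In the wider families, ATMYBR1 (Eucgr.F02372) differed by -1.77 ± 0.55, ANAC083 (Eucgr.H03387) by 1.23 ± 0.37, the stress-related RD26 (Eucgr.F01093) by 1.63 ± 0.61 and the xylem gene ANAC104 (Eucgr.I00191) by 0.72 ± 0.69. The 6 pectin genes had a median of 1.24, with PG2 (Eucgr.H02609) at least 2.72-fold brighter in high lignin (adjusted p = 0.765, limma), GATL3 (Eucgr.B03054) different by 2.02 ± 0.93 and GAUT6 (Eucgr.B01494) by -0.80 ± 0.43. The pectin median was 0.95 with PG2 at its bound, 0.33 without SW Mt. Garnet, 0.80 without Cardwell, 0.50 without Kupiano, 0.55 with normexp and 0.46 without the filter on dim probes. Of 8 expansins and related genes, ATEXPA6 (Eucgr.A01269) differed by 1.78 ± 0.60, ATEXLB1 (Eucgr.E00357) by 3.25 ± 1.28 and ATEXPA13 (Eucgr.C02271) by -1.37 ± 0.60. The former pair was well above background on 1 of 2 high holocellulose arrays. The median of this list was 0.14, and -0.13 with quantile normalization, -0.10 with median centring, -0.06 without Cardwell, -0.03 with the filter on all 4 arrays, 0.39 without a filter, 0.74 without Kupiano and 0.91 without N Kennedy River. None of the 18 MYB, 8 NAC, 6 pectin or 8 expansin genes passed over all probes or adjusted over their list alone, and these lists and that of the secondary wall regulators had camera adjusted p values of 0.839. The NAC family had a median of 0.34, and -0.03 without Kupiano, -0.02 without cross-hybridizing probes, 0.07 without the filter on dim probes and 0.15 without SW Mt. Garnet. It was 0.70 with the filter on all 4 arrays, 0.50 with the mean over the probes of a gene and 0.45 without N Kennedy River.

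None of the auxin, ethylene, homeodomain, tubulin or cell division lists held a gene that passed the test. Of 19 auxin genes 0 passed, with the dormancy-associated Eucgr.H04545 at 1.34 ± 0.37, the auxin carrier LAX2 (Eucgr.A00514) at -1.45 ± 0.47 and IAA14 (Eucgr.K03313) at -1.52 ± 0.51. Of 8 ethylene genes 0 passed, with ATEGY3 (Eucgr.G01188) at 1.61 ± 0.66, ERF1 (Eucgr.K03266) at 2.11 ± 1.64 and RAP2.3 (Eucgr.H03965) at 1.07 ± 0.95. Among 17 homeodomain genes Eucgr.B00377 differed by 1.53 ± 0.48, RVE1 (Eucgr.F02906) by 2.98 ± 1.88 and ATHB-12 (Eucgr.D02645) by -0.64 ± 0.52. TUA6 (Eucgr.F00470) differed by -0.69 ± 0.54, PLE (Eucgr.K00145) by 0.88 ± 0.69 and TUB3 (Eucgr.D01847) by -0.50 ± 0.51 among 8 tubulin and microtubule genes, and ATN (Eucgr.L01544) by -2.62 ± 0.81, PRL (Eucgr.H01043) by 1.77 ± 1.21 and the D-type cyclin Eucgr.F02302 by 0.56 ± 0.36 among 8 cell division genes. Another probe differed by 0.06 at ATHB-12, 0.05 at TUA6, 0.35 at Eucgr.H04545 and 0.66 at ERF1. LAX2 and ATN were well above background on 1 of 2 high lignin arrays, and ERF1, RVE1 and PLE on 1 of 2 high holocellulose arrays. The medians were 0.67 for ethylene, 0.23 for cell division, 0.08 for tubulins, 0.07 for auxin, -0.13 for homeodomain and -0.03 for MYB genes, and that of cell division turned to -0.02 with median centring, those of tubulins and auxin to -0.06 and -0.22 with quantile normalization and to -0.16 and -0.17 with median centring, and those of homeodomain and MYB genes to 0.04 and 0.10 with normexp. Without cross-hybridizing probes the median was 0.47 for MYB and -0.08 for auxin genes, with the mean over the probes of a gene 0.20 for homeodomain and -0.23 for auxin genes, without the filter on dim probes 0.24 for homeodomain genes, and with the filter on all 4 arrays 0.09 for MYB genes and -0.21 for tubulins. Without SW Mt. Garnet the medians were 0.13 for ethylene, which was 0.33 with quantile normalization, -0.68 for cell division, -0.22 for auxin, -0.06 for homeodomain and 0.003 for MYB genes. Without Cardwell they were -0.13 for auxin, -0.27 for tubulins and -0.41 for MYB genes, and without Kupiano 0.56 for cell division, 0.45 for auxin, -0.0006 for tubulins and 0.32 for homeodomain genes. Without N Kennedy River they were 1.02 for ethylene, 0.53 for cell division, 0.57 for tubulins, 0.41 for homeodomain and 0.26 for MYB genes. For MYB, homeodomain, tubulin, shikimate, auxin and cell division genes the camera direction, which compares test statistics with those of the other described genes, was down although the median or the mean was above 0. Of the 18 lists tested, 0 passed with the preset or with an estimated correlation.

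A second comparison asked whether the labelled grouping was the main division among the 4 arrays. SK1, well above background on all 4 arrays, parted the labelled groups by 2.88 log2 units, and the LAC17 model Eucgr.F04159 by 1.18. In contrast, the topoisomerase TOPII (Eucgr.H02748) stood between 0.15 and 1.09 on 3 arrays and at -9.20, not well above background, on the SW Mt. Garnet array, and the cellulose synthase IRX3 differed within high lignin. The labelled grouping parted 1558 probes (4.08%) without overlap by at least 1 log2 unit, against 1162 for SW Mt. Garnet with Kupiano and 771 for SW Mt. Garnet with N Kennedy River. The filter kept probes bright in 1 labelled group and dim in the other, but dropped such probes of the other groupings. It therefore favoured the labelled grouping. With 3 possible groupings no test can reach 0.05. After normexp the numbers were 565 and, for the higher of the other groupings, 547, and among the 34083 probes well above background on all 4 arrays they were 814 and 773, an alternative chosen after the data were seen. Without a minimum gap, 39.5% of the probes separated the labelled groups. The 33.3% of 3 equal groupings is no measure of chance here, since the filter favoured the labelled grouping. Array correlations across probes ran from 0.873, between SW Mt. Garnet and N Kennedy River, to 0.915, between SW Mt. Garnet and Cardwell, and the pair within high lignin correlated at 0.905, below Cardwell with Kupiano at 0.914 and Cardwell with N Kennedy River at 0.911, both across the groups. The smallest median absolute difference between arrays, 0.451, was also across the groups, between Cardwell and Kupiano. Probes are not independent replicates. On the first principal component, with 46.7% of the variance, the arrays lay in the order SW Mt. Garnet, Cardwell, Kupiano and N Kennedy River, at -169.5, -6.74, 61.4 and 114.9.

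The third comparison described each provenance, with 1 array each and therefore no test. On the SW Mt. Garnet array, UGT72B3 stood at 1.96 with another probe, 7.26 log2 units above the nearest array, a phosphotriesterase family gene (Eucgr.J02524) 5.39 and a wound-responsive gene (Eucgr.E03810) 4.26 units above. TOPII (Eucgr.H02748), a topoisomerase, stood at -9.20 there, 9.35 units below the nearest array, a hydroxyproline-rich glycoprotein (Eucgr.I02624) 6.83 units and Eucgr.I02049 6.63 units below. Cardwell was highest for an F-box gene (Eucgr.A00241) by 4.88 units, for the terpene synthase TPS02 (Eucgr.K00881) by 3.96 and for a clathrin adaptor gene (Eucgr.H05014) by 3.55. It was lowest for AAE14 (Eucgr.D00173) by 4.68, for the diacylglycerol kinase DGK5 (Eucgr.F03363) by 4.61 and for UGT88A1 (Eucgr.D00095) by 4.43. Kupiano was highest for a gene of the elongation factor Spt5 (Eucgr.E02910) by 7.57, for Eucgr.D00273 by 6.40 and for an AT-hook gene (Eucgr.D01853) by 5.92. It was lowest for an F-box gene (Eucgr.H02934) by 6.05, for the splicing factor SR33 (Eucgr.H03400) by 4.96 and for a steroid dehydrogenase family gene (Eucgr.H01470) by 4.82. N Kennedy River was highest for a nodulin-like transporter (Eucgr.B03946) by 4.16, for the sucrose synthase SUS6 (Eucgr.J01640) by 3.99 and for MEE23 (Eucgr.D01614) by 3.50. It was lowest for a small chaperone (Eucgr.L02712) by 6.92, for a Rossmann-fold protein (Eucgr.G02325) by 5.85 and for the glycosyltransferase GT72B1 (Eucgr.A02713) by 5.73. Where the low array was not well above background, these distances depend on the values the scanner software gives to such spots. Another probe of Eucgr.J02524 differed between the groups by -1.46, against -4.58 for the probe named. Other probes of these genes were set against the named ones only by the difference between the groups, not by the distance of the array named. They disagreed in the sign of that difference at 4 of these genes. They differed by -1.23 and 0.45 at Eucgr.D01853, whose named probe was not well above background in high holocellulose, by -1.69 and 0.17 at Eucgr.H02934, against -4.53 for the probe named, by 0.42 and 1.20 at Eucgr.H01470, against -2.17, and by 0.40 at TPS02, against -1.52.

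Over all tested probes, 2653 probes lay at least 1 log2 unit below and 1586 above every other array on the SW Mt. Garnet array. The numbers below and above were 877 and 857 for Cardwell, 1451 and 1162 for Kupiano, and 1714 and 1361 for N Kennedy River. With median centring the SW Mt. Garnet array had 1811 probes below and 3080 above, and N Kennedy River 2189 below and 1002 above, and after normexp Cardwell had 233 below and 498 above, so the balance of the directions moved with the scaling. Replicate spots of 7 spike-in control probes, all well above background, had a median SD between 0.04 and 0.11 log2 units on an array. An ERCC control probe well above background had SDs from 0.27 to 0.30 on 3 arrays, and a dimmer one, with at most 65.7% of its spots well above background, from 0.53 to 0.70 on the 4 arrays.

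**Figure D3:**
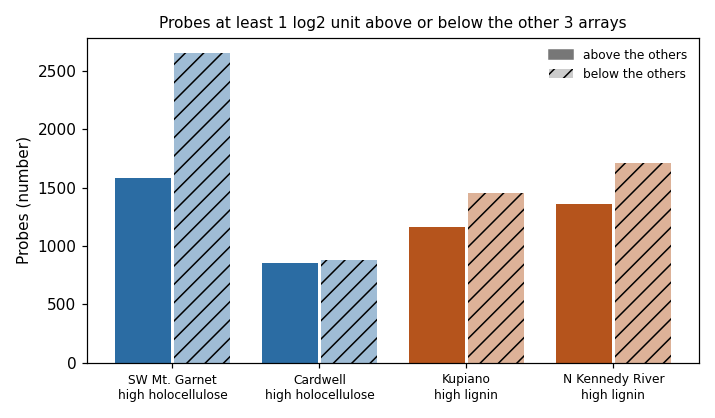
Number of probes (vertical axis, from 0) that lay at least 1 log2 unit above (plain bars) or below (hatched bars) all 3 other arrays, for each provenance, coloured by group. The SW Mt. Garnet array has the most, 1586 above and 2653 below, and the Cardwell array the fewest, 857 and 877.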

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

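Of the tests in this part, that of the clock genes was chosen only after the result was seen and its morning genes were matched on Arabidopsis loci later still. Chosen after their results were also the use of bootstrap intervals to decide the tests of medians and ratios and the look at all photosynthesis genes on the array. Of 25 control probes outside the comparisons, 12 named ERCC and 13 named ETG, 2 had every spot well above background on 3 arrays. A further 5 had part of their spots well above background on at least 1 array, the brightest of them 1.23, 1.33, 2.42 and 2.49 log2 units above the negative control spots on Cardwell, Kupiano, N Kennedy River and SW Mt. Garnet. An ERCC probe stood 5.21, 5.29 and 6.30 log2 units above the negative control spots on the Cardwell, Kupiano and N Kennedy River arrays, with every spot well above background, and 0.80 units above them on the SW Mt. Garnet array, with 0% of its spots well above background. An ETG probe stood 4.88, 5.36 and 6.24 units above the negative control spots on the same 3 arrays and 1.33 on SW Mt. Garnet, also with 0% of its spots well above background there. No explanation was tested for either probe.

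More probes stood apart on the SW Mt. Garnet array, 4239, than on N Kennedy River, with 3075, Kupiano, with 2613, or Cardwell, with 1734. For 1067 genes other tested probes shared no stretch of 15 bases with the probe standing apart. They moved in its direction by a median of 0.76 of its own shift (bootstrap 95% interval 0.73 to 0.79). For these genes this speaks against a sequence variant under the single probe as the whole cause, as far as tested probes go. Probes too dim to be tested were left out. The cross-hybridizing probes among the named genes had no other tested probe, so the test could not exclude cross-hybridization. The scale of the array stays open, since the brightest spike-in probe stood 0.80 log2 units higher on that array than on the mean of the others and the dimmest differed by -0.23, and the ratio to the next array was 1.38, 1.19 with quantile normalization, 1.53 with median centring and 1.54 with normexp. Quantile normalization did not remove the excess, but the bound of 1.5 set for ruling out the scale lay above the starting ratio, so this test could not exclude it. A difference of the provenance itself stays open and cannot be told apart from the sample, since each provenance had 1 array.

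The groups lay at least 2 log2 units apart without overlap at 372 probes. Other tested probes of the same genes followed with a median of 0.64 of the difference (interval 0.53 to 0.80, 107 genes). Only tested probes entered this ratio. The filter left out other probes that stayed dim, such as a PSBR probe that differed by 0.26, against 4.54 for the probe named. The ratio may therefore be too high. It speaks against effects of single probes as the whole cause only as far as tested probes of these 107 genes go. Genes without another tested probe were not covered, among them those named by a cross-hybridizing probe. In 199 of the 372 probes (53.5%) one group had no array well above background, and among probes bright on all 4 arrays the labelled grouping gave 98 such probes against 134 for another grouping, a ratio of 0.73. The excess of wide gaps in the labelled grouping may come from spots at background and their surrogate values. The filter also admitted probes dim in 1 labelled group but not those dim in a pair of another grouping. It can make such an excess by itself, and these sources cannot be told apart here. A difference tied to wood composition stays untested beyond this, because 2 arrays against 2 give only 3 groupings.

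The 5 photosystem genes had a median difference of 1.51, with a camera adjusted p of 0.254 (0.873 with an estimated correlation). Of the 5, 3 were higher on both high lignin arrays. Among these, PSBR and PSAK passed the filter only through high lignin. A PSBR probe too dim to be tested differed by 0.26. Without the filter on dim probes the median was 1.06 over 23 genes. With an array left out, the tested genes of the list changed. The median was 0.51 over 7 genes without SW Mt. Garnet, 1.60 over 11 without Kupiano and 3.30 over 10 without N Kennedy River. Where a high lignin array was left out, the filter let in genes for being bright on the other. Green cells from bark or leaf are a candidate source that stays open. The median difference of other chloroplast genes was 0.37 over 19 genes (interval -0.21 to 0.75), so neither a shift of 1 nor one under 0.5 was shown, and many of these genes serve plastids that are not green. On the Kupiano array LHCA6, PSAN, LHCB2.4 and LHCB4.3 stood between -4.89 and -3.87, and at or below -7.44 on the other arrays, and the Rubisco large chain RBCL (Eucgr.B03944) at -4.06 on Kupiano and at or below -6.54 elsewhere, while the Rubisco small chain RBCS1A (Eucgr.K02223), known as abundant in leaves, stood at -6.71 on Kupiano and -6.05 on N Kennedy River, PSB28 at -5.16 and -2.83, and Rubisco activase RCA at -5.79 and -4.56, with -5.17 on SW Mt. Garnet, and RBCS1A Eucgr.J01502 was well above background on no array. A different time of day at sampling also stays open, because the 4 evening clock genes had a median of -0.11 while only 2 morning clock genes could be tested, RVE1 at 2.98 ± 1.88 (-8.97 on SW Mt. Garnet, between -3.48 and -3.12 elsewhere) and Eucgr.D02320 at 0.23 ± 0.44, and so does the wood composition of the groups, as untested.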

How the results depend on the processing

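The alternatives without cross-hybridizing probes, with all tested genes as background, with genes joined by symbol, with 1 bright array in place of 3, with an estimated correlation in each setting that gave a list call and, for the groupings, on probes well above background on all 4 arrays were chosen after seeing the data. The numbers of probes past the threshold were 0 in both directions under every alternative that kept the test, with a smallest adjusted p between 0.145 and 0.798, and from 0 to 0 with each array left out, where the lone array of a group is assumed to vary like the pair. In a design of this size that says little about stability. Groups without overlap and a mean difference of at least 1 held 3105 probes higher and 2297 lower in high lignin. The number of gene lists past the threshold was 0, but 1 with the mean over the probes of a gene (flavonoid biosynthesis, adjusted p 0.0382), 3 with all probes of a list, and 0 to 1 with an array left out. The 3 were flavonoid biosynthesis, photosynthesis markers and shikimate and phenylalanine biosynthesis, whose median turned from 0.14 to -0.74, since 3 of the 8 probes were then of SK1. All probes count several probes of one gene as members at the preset correlation of 0.01. With an estimated correlation each of these settings gave 0 lists, with adjusted p of 0.913, 0.914, 0.976 without Cardwell and 0.952 without N Kennedy River. The range of the smallest list adjusted p over all alternatives was 5.45e-05 to 0.976. Median centring moved the median difference of all tested probes from 0.002 to -0.24, and with it 5 of 18 list medians changed sign, against 4 with quantile normalization, 2 with normexp, and 8 without SW Mt. Garnet. Of the 80 named probes outside the widest gaps, 20 changed sign under at least 1 alternative, and of the 20 with the widest gaps 0 did. Those 20 were chosen for wide gaps between the groups. Leaving out an array could not turn their sign, so the 0 does not speak for stability. With normexp, the median ratio of the named differences to those reported was 0.48. That setting changed the input intensities, the background correction and the offset together, and which of them shrank the differences was not tested. The share of probes parted by the labelled grouping was 4.08%, 1.48% with normexp, 11.4% with a gap of 0.5 and 2.39% among probes well above background on all 4 arrays, and the cause was not tested. Leaving out an array was not run for the groupings and the provenances, which need all 4. For the probes standing apart, normexp gave 1698 below for SW Mt. Garnet, 498 above and 233 below for Cardwell, 575 above and 552 below for Kupiano, and 819 above and 994 below for N Kennedy River. Median centring gave 3080 above for SW Mt. Garnet. A difference of 2 in place of 1 gave 256 above and 903 below for SW Mt. Garnet, 229 and 206 for Cardwell, 294 and 446 for Kupiano, and 311 and 552 for N Kennedy River, fewer by construction. The causes of the other shifts were not tested. No paired analysis was possible because the labels give no replicate numbers that pair samples across the groups. Differences of probes at background are limited by the lowest signal told from it, between -6.87 and -5.34 on the log2 scale used here.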

Other observations

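The dehydration test of this part was set before its result was seen, but the bootstrap interval that decides it was chosen after its median had been seen. Several gene lists stood apart on single arrays, given as the median of their genes on that array minus the mean of the other 3 and as its percentile among 10000 random lists matched on mean expression, a description of 18 lists on 4 arrays without a test, from which those below were chosen after their values were seen. Each kept its sign with quantile normalization, median centring and normexp, but not its size. With normexp, laccases on SW Mt. Garnet were at 0.18, pectin genes there at -0.87, flavonoids there at 0.79 and on N Kennedy River at -0.89, secondary wall genes on N Kennedy River at 0.62 and monolignol genes on Cardwell at 0.52. With median centring, heat shock genes on SW Mt. Garnet were at -0.24. Flavonoid genes were at 1.63 on SW Mt. Garnet (percentile 99.98) and at -1.39 on N Kennedy River (percentile 0.20). Heat shock and chaperone genes were at -0.57 on SW Mt. Garnet (percentile 0.47) and at 0.41 on Kupiano (percentile 99.55). Monolignol genes were at 0.94 on Cardwell (percentile 99.1), where CCOAMT stood at -0.29, against -7.17 on SW Mt. Garnet. The secondary wall NAC and MYB genes were at 1.49 on N Kennedy River (percentile 98.8), laccases at 0.95 on SW Mt. Garnet (percentile 97.9) and pectin genes at -2.10 on SW Mt. Garnet (percentile 2.18).

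RD29B and AtGolS2, genes known for their response to dehydration and abscisic acid, were among the widest gaps in favour of high lignin. Both were read by probes named as cross-hybridizing by the array's design, with no other tested probe. A hypothesis is that the dehydration response as a group was higher in the high lignin samples. Over the other 21 tested genes of such a list, drawn up after these values were seen, the median difference was 0.29 (bootstrap 95% interval -0.06 to 0.66, camera p 0.677), and 19.0% stood higher on both high lignin arrays, against 24.1% of all described genes. The values give no support for a shift of 1 log2 unit in the group, and a smaller one stays open. A further AtGolS2 model (Eucgr.L03244) was among them.

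Provenances also differed within a group. Between SW Mt. Garnet and Cardwell 27.6% of the tested probes lay at least 1 log2 unit apart, and between Kupiano and N Kennedy River 24.7%.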
